A study of Homo sapiens with 3 samples.

How the data were processed

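Total RNA of HCT116 cells, a human colorectal carcinoma line, was labelled with Cy3 and read on 3 Agilent arrays, each holding 1 sample. The groups were a control, 5 µM UNC1999 and 10 µM GSK343, with 1 array per group. Per the labels' protocols, RNA was amplified and labelled with a low-input kit from Agilent. The titles, the treatment protocol and the design text give an exposure of 4 h, while the source names of the treated samples give 6 h. The labels give neither a vehicle nor an exposure time in the name of the control.

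Per the file headers, each spot's intensity was extracted with Agilent Feature Extraction 10.5.1.1 from array design 028004, on a linear scale. The processed signal used here had already been background-corrected by that software. The authors also deposited a table of intensity values per probe. Its values equalled the scanner files' processed signals, averaged over the spots of a probe, within 0.0001 for all 42405 probes compared on the control and GSK343 arrays and all 42403 on the UNC1999 array. The column medians were 300.5 (control), 248.8 (UNC1999) and 260.1 (GSK343). The table was therefore linear, not scaled between arrays and not centred, and nothing in its scale, centring or direction stayed unknown.

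Each array carried 58717 spots that were not controls, for 42405 probes. Spots marked as outliers by the software were left out (348, 393 and 486 on the control, UNC1999 and GSK343 arrays), and 0 spots were saturated. The log2 processed signal was averaged over the spots of a probe, and the array's 75th percentile was subtracted. A gene was read by its probe with the highest mean signal over the 3 arrays, among probes well above background on at least 1 array. It counted as measured in a comparison where that probe was well above background on both arrays. For a gene whose probes were all not well above background on 1 of the arrays, the brighter signal was set against a value for the dim array. That value was the higher of the dim probe's signal and the lowest signal well above background on that array, and the ratio is called its bound. Such a bound is an estimate and no strict limit, since the true level of a dim gene can lie above the value used. Symbols were taken from a RefSeq table of assembly GRCh38.p14, used for names only, through the accession of the probe; 27235 of 42405 probes matched, and others kept the name in the files. Probe coordinates are those of the files, on hg19.

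With 1 array per group there was no replicate error and no p-value was computed. Genes were counted at a ratio of 2-fold or more. The scanner software's own error of a ratio, which covers spot and scanner error but neither cultures nor labelling, is given as a log2 value. For bright genes it follows from a fixed multiplicative error of 0.1 per signal, so it does not measure the error of single probes. The number of arrays limits the precision of every value. The 29 gene lists, the rule for named genes, the comparisons and all alternatives were fixed before the data were examined, except where stated. A list's median log2 ratio was set against 10000 random lists of the same size, matched on signal in 20 bins, and described as outside when it left their central 95%. By chance 1.45 of the 29 lists would do so per comparison if the genes of a list varied independently. Lists whose genes vary together between cultures or labellings can leave the range more often, which the random lists do not measure. The rule for named genes took EZH2 and EZH1, up to 10 genes with the largest and 10 with the smallest ratio of 2-fold or more among genes at or above the median signal, 3 members of each list per compound, a fixed set of 10 genes and 3 bounds per direction. Among the genes of largest and smallest ratio, those whose other measured probes had the opposite sign were skipped, as were transcripts named only by locus, Ensembl or noncoding records; list members and fixed genes were taken whatever their other probes gave. Not every gene the rule took is reported here. Symbol pools also left out names that begin like clone or predicted-transcript records, which is stricter than the fixed rule for single genes. This pool was narrowed further after results had been seen and then returned to its first form; the narrower pool is given as an alternative.

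Both treated arrays share the control array, so 100 sets of 3 unchanged arrays were simulated. Their noise was drawn, within 20 signal bins, from the difference between the UNC1999 and GSK343 arrays, and therefore includes any real difference between the compounds. All simulated arrays drew from the same noise, so higher and lower counts were equal on average by design. The same functions were tested on simulated data for UNC1999 against control, over 28179 genes. Of 50 genes altered at each size, 3 passed 2-fold at a true 1.5-fold, 29 at 2-fold, 48 at 3-fold and 50 at 4-fold, and 56 of 27979 unaltered genes passed. Over 18935 genes with a symbol, a simulated list moved by 0.30 had a median of 0.25 above every random list, and an unmoved list lay at percentile 30.4.

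The alternatives were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile and cyclic loess normalization, scaling to the median of probes well above background, the deposited table without scaling, no filter on dim probes, genes at or above the median signal, the mean over a gene's probes, and a 1.5-fold threshold. A count was taken as kept within a factor of 1.5, a list median when it held its sign and moved by less than 50% of the width of its central range, a correlation within 0.05, and a single gene within its scanner error. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Exon and UTR positions of the probes were not analysed here, since no annotation on hg19 was used.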

Results

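To ask which genes respond to inhibitors of EZH2, the histone H3K27 methyltransferase of the PRC2 complex, HCT116 colorectal carcinoma cells had been exposed to 5 µM UNC1999 or 10 µM GSK343. Both compounds compete with the methyl donor SAM and share a pyridone and indazole carboxamide scaffold, and UNC1999 also inhibits EZH1. Among their differences is the substituent on the piperazine nitrogen, isopropyl in UNC1999 and methyl in GSK343. Gene expression was measured on 3 Agilent arrays, 1 each for the control, UNC1999 and GSK343, after 4 h according to the titles and 6 h according to the source names. No difference given here has a replicate check. Of 42405 probes, 38429 (90.6%) were well above background in the control, 37195 (87.7%) with UNC1999 and 36934 (87.1%) with GSK343. The median SD between spots of a probe was 0.079, 0.089 and 0.063 log2 units on these arrays. The scanner error of a ratio was 0.20 for bright genes. The 9 labelling spike-ins well above background on all arrays had median log2 ratios of 0.010 for UNC1999 and -0.021 for GSK343 against the control. All arrays came from 1 slide and 1 scan, and each group held its own array position, so that position and group cannot be told apart.

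Genes of cholesterol synthesis and uptake were higher with UNC1999 than in the control. All 25 measured members had a log2 ratio above 0, and their median of 0.44 (1.36-fold) exceeded those of all 10000 random lists. INSIG1, which retains the SREBP activator complex in the endoplasmic reticulum (ER), had a log2 ratio of 1.42 (2.67-fold). It ranked 1 of 11704 genes with a symbol at or above the median signal. HMGCS1, an enzyme early in the pathway, had a log2 ratio of 0.89, MVK of 0.85 and MSMO1 of 0.84. Fatty acid synthesis genes, a list that also holds INSIG1, had a median of 0.18 with 14 of 18 members above 0, and LPIN1 had a log2 ratio of 0.83, with other probes at 0.26 and 0.70. Without scaling between arrays, the cholesterol and fatty acid medians were 0.29 and 0.033.

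Regulators of the integrated stress response, the ATF4 and CHOP branch, were likewise higher with UNC1999. Of 25 members, 22 were above 0, and the median of 0.29 (1.23-fold) exceeded those of all random lists. DDIT4, an inhibitor of mTORC1, had a log2 ratio of 1.02 (2.03-fold), CHAC1, which degrades glutathione, of 0.63 (0.23 by its other probe), GDF15 of 0.57, DDIT3 (CHOP) of 0.46 and ATF4 of 0.42. FGF21 and VLDLR of the same list were lower, with log2 ratios of -0.98 and -0.74, though another probe of VLDLR gave 0.0050. Both were dim, with control signals of 114.0 and 86.4 against an array median of 300.5. Amino acid genes had a median of 0.12 with 22 of 30 above 0, and SLC7A11, the cystine transporter, had a log2 ratio of 0.94. ER chaperones and degradation genes had a median of 0.10 with 20 of 27 above 0, and HERPUD1 (0.76), HSPA5 (0.53) and DNAJB9 (0.53) were among the higher members while CALR was at -0.28. Without scaling between arrays, where the median of all genes was -0.20 rather than -0.045, the integrated stress response median was 0.14 and those of the amino acid and ER lists turned to -0.031 and -0.049.

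Immediate early genes had a median of 0.26 with UNC1999, 20 of 25 being above 0, and EGR1, a zinc finger transcription factor, had a log2 ratio of 0.68, while FOSL1 was at -0.56. NF-kappaB and inflammatory genes had a median of 0.21 with 11 of 17 above 0, among them RELB (0.40) and CXCL1 (0.40, with another probe at -0.0060). Without scaling these lists had medians of 0.11 and 0.062. PRC2 subunits and H3K27 demethylases had a median of 0.14 with 9 of 13 above 0, which became -0.0072 without scaling. EZH2 itself (probe at chromosome 7, 148504505 to 148504564) had a log2 ratio of 0.25, and EZH1 (chromosome 17, 40852674 to 40852733) of -0.17. The scanner error was 0.204 for both, a value that bright genes share and that was not measured for these probes. EZH2 ranked only 1169 of 11704 bright genes with a symbol. Its signals without scaling were 13727.7 in the control and 14737.4 with UNC1999. Developmental and tumour suppressor genes known as PRC2 targets had a median of -0.032, at percentile 45.4 of the random lists, with 13 of 30 above 0. The sign of this median changed with the processing, turning positive with normexp, with median scaling and among genes above the median signal. SOX1, a neural transcription factor, had the lowest log2 ratio of that list, -0.91, but it was dim, with signals of 77.5 in the control and 37.3 with UNC1999. BMPR1B (-0.66) and SOX17 (-0.44) were dim too, with control signals of 88.6 and 85.1.

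Autophagy genes, the machinery and its receptors, had a median of 0.089 with UNC1999 and 22 of 35 members above 0. This lay at percentile 97.2, just inside the central 95% of the random lists, and 8 of 20 further draws of random lists put it outside. ATG2B (0.46), OPTN (0.41) and WIPI1 (0.40) were among its higher members, while the cargo receptor SQSTM1 was at 0.064 and MAP1LC3B (LC3B) at 0.093, with another probe at -0.085. Without scaling the median was -0.062. The list medians inside their random ranges were 0.034 for lysosome, -0.033 for metallothioneins and zinc export, 0.036 for p53 targets, -0.011 for G2 and mitosis, 0.014 for G1/S and DNA replication, 0.0070 for NRF2 targets, 0.0285 for heat shock, 0.026 for ERK output and 0.049 for hypoxia and glycolysis. They were -0.0325 for interferon-stimulated genes, 0.0017 for WNT targets, -0.018 for ribosome biogenesis, -0.035 for BCL2 family, -0.012 for ribosomal proteins and -0.0038 for reference genes. Markers of tissues had medians of -0.042 (intestinal epithelium), -0.076 (fibroblast), -0.18 (leukocyte) and -0.21 (endothelial). In all, 8 of 29 lists lay outside their range.

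At 2-fold or more, 22 genes and transcripts were higher and 244 lower with UNC1999 among 28693 measured, so that 8.27% of them were higher. That share was 24.1% after quantile normalization, 18.3% after cyclic loess, 18.3% with median scaling and 2.33% without scaling. In simulated unchanged arrays, 22 to 49 were higher and 20 to 56 lower, against 21 and 237 observed over the same 28179 genes. The simulation treats both directions alike, so it could not give an excess of lower genes even from a technical cause. The observed ratios had a median of -0.096 among the 7174 dimmest genes. Of the 244 lower genes, 130 lay among the 7174 genes with the dimmest signal and 5 among the 7173 with the brightest. Besides INSIG1 (chromosome 7, 155101843 to 155101902) and DDIT4 (chromosome 10, 74035363 to 74035422), the bright genes 2-fold higher were ARRDC4 (1.02), an arrestin family member, and ND6 (1.03), a complex I subunit encoded by mitochondrial DNA. The lowest bright genes with a symbol that the rule took were RPL13AP3 (-1.43), RPS12 (-1.08), OR51I2 (-1.05), CSAG4 (-1.03) and HOPX (-1.03). RPL13AP3, RPS12 and CSAG4 were each read by 1 probe, and the other probe of OR51I2 gave -0.046. Of genes well above background on 1 array only, 17 were 2-fold or more higher and 117 lower by their bounds, which are estimates. OR5P3 had a bound of 6.39-fold higher and CER1 of 4.88-fold lower.

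**Figure D1:**
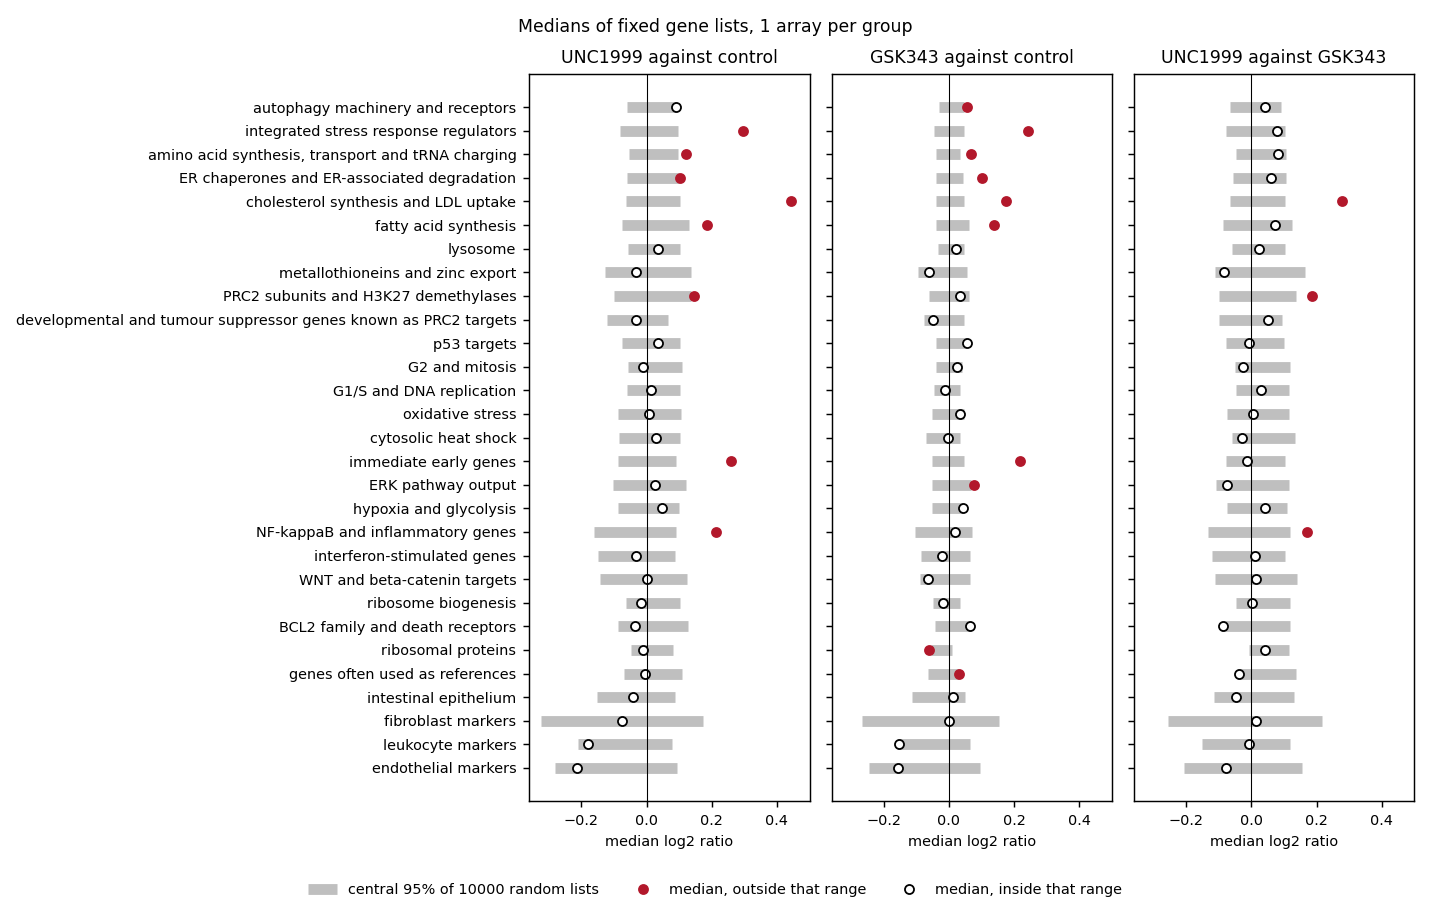
Median log2 ratio of the 29 gene lists in each comparison (horizontal axis, log2 units), with grey bars for the central 95% of 10000 random lists matched on signal. Filled points lie outside the bar: cholesterol synthesis is at 0.44 for UNC1999 and 0.18 for GSK343 against control, and at 0.28 between the compounds.

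With GSK343, the integrated stress response list had the highest median, 0.24 (1.18-fold), with 21 of 25 members above 0 and above all random lists. CHAC1 and DDIT4 had log2 ratios of 0.79 and 0.79 and ranked 2 and 3 of 11633 bright genes with a symbol, though another probe of CHAC1 gave 0.34. The nuclear receptor NR4A3, chosen after its values were seen because it ranked first, was at 0.81. Immediate early genes had a median of 0.22 with 20 of 25 above 0, among them NR4A2 (0.79, or 0.57 by its other probe), EGR1 (0.62) and FOS (0.50). GDF15 was at 0.47, DDIT3 at 0.41, ATF4 at 0.15 and the dim gene FGF21 at -0.89. Without scaling the medians of the integrated stress response and immediate early lists were 0.11 and 0.088. All list medians against control use the same control array for both compounds. A list higher with both was therefore not repeated independently, since low values on that array would raise both medians.

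Cholesterol genes had a median of 0.18 (1.13-fold) with GSK343, with 24 of 25 above 0 and above all random lists. INSIG1 had a log2 ratio of 0.60 (1.52-fold), MSMO1 of 0.36, MVK of 0.26 and HMGCS1 of 0.25. Fatty acid genes had a median of 0.14 with 18 of 18 above 0, and LPIN1 was at 0.42, with other probes at 0.34 and 0.12. ER chaperone genes had a median of 0.10 with 22 of 27 above 0, including DNAJB9 (0.52), HERPUD1 (0.37) and HSPA5 (0.26), while CALR was at -0.47. Amino acid genes had a median of 0.068 with 25 of 30 above 0, and SLC7A11 was at 0.45. Autophagy genes had a median of 0.054 with 25 of 35 above 0, at percentile 99.1, and UVRAG was at 0.24, SQSTM1 at 0.078 and MAP1LC3B at 0.035, with another probe at 0.23. Without scaling, where the median of all genes was -0.16 rather than -0.0255, the medians of the cholesterol and fatty acid lists were 0.044 and 0.0067 and those of the ER, amino acid and autophagy lists -0.031, -0.063 and -0.077.

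PRC2 subunits had a median of 0.034 with GSK343, and EZH2 and EZH1 were at -0.030 and 0.035, both within their scanner error. PRC2 targets had a median of -0.050 with 7 of 29 above 0, at percentile 10.7, and the dim gene SOX1 was at -0.70. ERK output genes had a median of 0.078 with 14 of 17 above 0, which was -0.054 without scaling. Reference genes had a median of 0.032, at percentile 97.9 and outside their range, which was -0.10 without scaling. Ribosomal protein genes had a median of -0.061 with 24 of 30 below 0, at percentile 1.34 and also outside. It turned to 0.0069 after cyclic loess and 0.0022 with median scaling. The medians of p53 targets (0.054, percentile 97.45) and BCL2 family genes (0.064, percentile 97.48) lay at the edge of the range, and 20 and 15 of 20 further draws put them outside. Inside their ranges were lysosome (0.0225), metallothioneins (-0.060), G2 and mitosis (0.025), G1/S (-0.011), NRF2 targets (0.033), heat shock (-0.0023), hypoxia (0.0425), NF-kappaB genes (0.019), interferon-stimulated genes (-0.020), WNT targets (-0.063) and ribosome biogenesis (-0.018). So were markers of intestinal epithelium (0.012), fibroblasts (0.0010), leukocytes (-0.15) and endothelium (-0.15), and 10 of 29 lists lay outside. These 10 include the reference and ribosomal protein genes, so a small median outside its range need not be a response to the compound.

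At 2-fold or more, 30 genes were higher and 119 lower with GSK343 among 28518 measured, 20.1% of them higher. That share was 37.0% after quantile normalization, 35.9% after cyclic loess, 31.9% with median scaling and 7.76% without scaling. Simulated unchanged arrays gave 25 to 58 higher and 26 to 53 lower, against 26 and 116 observed over 28179 genes. Here too the simulation could not give an excess in one direction. No bright gene with a symbol was 2-fold higher. The lowest bright genes that the rule took were RPL13AP3 (-1.93), RPS12 (-1.43), CSAG4 (-1.29) and NDUFA6 (-1.14), a nuclear-encoded complex I subunit, each read by 1 probe. By bounds, 22 genes were 2-fold or more higher and 86 lower, among them OR4C11 (8.71-fold higher), OR6C1 (4.75-fold lower) and KCNT2 (4.44-fold lower).

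Set side by side at their different doses, cholesterol genes were higher with 5 µM UNC1999 than with 10 µM GSK343 in 22 of 25 cases, with a median log2 ratio of 0.28 above all random lists. INSIG1 was 0.82 higher and HMGCS1 0.64 higher with UNC1999. PRC2 subunits had a median of 0.19 (percentile 99.7) with 10 of 13 higher, and EZH2 differed by 0.28. NF-kappaB genes had a median of 0.17 (percentile 99.6) with 14 of 17 higher. The remaining 26 lists lay inside their ranges, including the integrated stress response (0.078), autophagy (0.042) and immediate early genes (-0.014). A value inside the range does not show that the compounds acted alike.

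Between the compounds, 44 genes were 2-fold higher and 66 lower with UNC1999 among 28209 measured. The bright ones with a symbol were both mitochondrially encoded: ND6 (mitochondrial genome, 14449 to 14508), with a log2 ratio of 1.09, and ND5, with -1.12. By bounds, 41 were 2-fold or more higher and 49 lower, among them KRTAP19-6 (4.21-fold higher) and KLHL1 (4.92-fold lower). Of 28179 genes measured on all arrays, 3 were 2-fold higher with both compounds, 41 lower with both and 0 in opposite directions. FLJ34223, chosen after its values were seen, was among the 3, and the other two were transcripts named only by a sequence record. Simulated unchanged arrays shared 5.23 higher and 5.59 lower genes on average, with at most 11 lower, and independent lists would share 0.019 and 0.98. The simulated lists of lower genes were shorter, with means of 36.08 and 35.50 against 237 and 116 observed. Their overlap is therefore no measure for lists of the observed length. Log2 ratios against the control correlated across genes with Pearson's r = 0.52 and Spearman's rho = 0.45, genes not being independent replicates, and r was 0.50 (0.49 to 0.51) in simulated arrays. The covariance was 0.035 against 0.034 (0.033 to 0.035) in simulated arrays. Part of the overlap of lower genes may come from the shared control, which cannot be split.

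**Figure D2:**
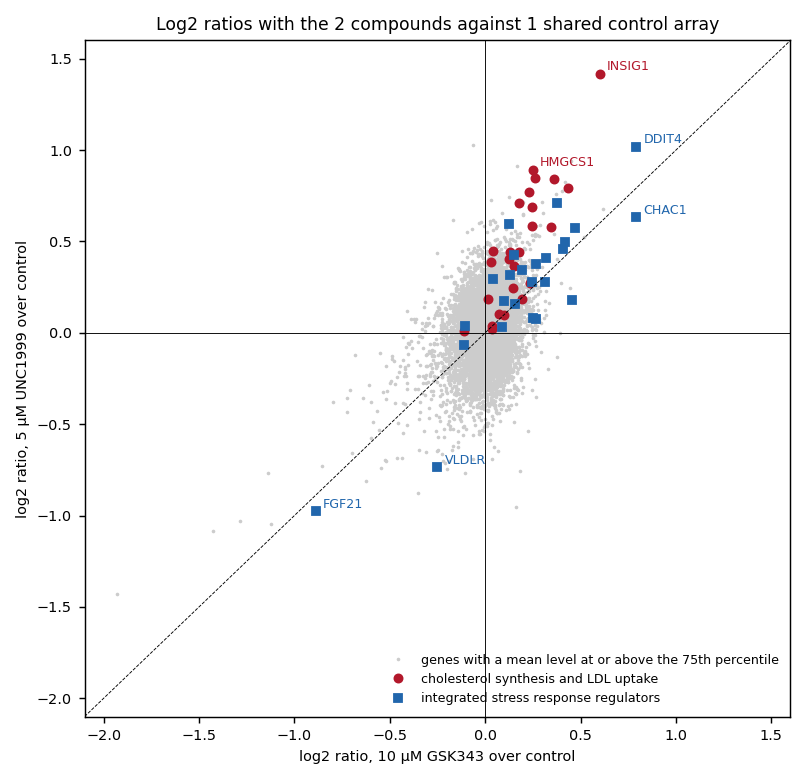
Log2 ratio with 5 µM UNC1999 (vertical axis) against that with 10 µM GSK343 (horizontal axis), both over the same control array, with 1 point per gene and the dashed line marking equal ratios. Grey points are genes with a mean level at or above the 75th percentile, red circles cholesterol genes and blue squares integrated stress response genes; INSIG1 is at 1.42 and 0.60, DDIT4 at 1.02 and 0.79.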

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

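Tests chosen only after the result was seen were those of independent probe errors, of bright signals, of cultures and array positions, of nearness to background and of pairs of probes. The other tests were set before their own values were seen. Genes and lists on opposite sides of 0 with the compounds are given as UNC1999 minus GSK343 in log2 units. Differences of single genes were not tested, and the lists all lay inside their random range when the compounds were compared directly. For single genes the difference was 0.28 for EZH2, -0.21 for EZH1, 1.09 for ND6, -1.12 for ND5, -0.19 for CDKN1A, 0.21 for MYC (whose other probe gave -0.081 with UNC1999), 0.44 for OPTN and 1.02 for the unnamed transcript THC2716057. For lists, the median with GSK343 was subtracted from that with UNC1999, both against control. This gave -0.037 for G2 and mitosis, 0.025 for G1/S, 0.031 for heat shock and 0.065 for WNT targets. It gave -0.099 for BCL2 family genes, -0.035 for reference genes, -0.054 for intestinal epithelium and -0.0775 for fibroblast markers. Medians of the direct ratios between the compounds differ from these. They had the opposite sign for heat shock (-0.0295) and fibroblast markers (0.0155), and that of WNT targets was 0.013. Against control, each of these lists lay inside its random range with at least 1 compound.

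Cholesterol genes were higher with UNC1999. A trend with signal strength was argued against, since the median after cyclic loess was 0.4256, with random lists between -0.079 and 0.090. Independent errors of the probes were argued against too, since 25 of 25 genes, each read by its own probe, lay above 0, in a list fixed beforehand. The planned test of faults of single probes could not decide. It had 4 other probes, from LSS and HSD17B7 only, with a median of 0.4735, and 5 had been planned as the minimum. With 1 array per group, a response to the compound cannot be told apart from a difference between cultures or array positions.

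The 12 mitochondrial genes with mRNA from the heavy strand, a set chosen after its values were seen, were all lower with UNC1999. Their median was -0.45 (-0.95 to -0.19), while ND6 of the light strand was at 1.03. Some of these genes share an mRNA, so they are not 12 separate readings. With GSK343 the 12 genes had a median of 0.046. Compression of bright signals was argued against, since the set lay at percentile 0 among sets drawn from 191 genes of nearest brightness. Labelling less dependent on poly(A) tails stayed open. It would raise histone mRNAs, which lack a tail, but their median was -0.2821 and, against GSK343, -0.15 (32 of 43 below 0). The test cannot decide, since these mRNAs were lower with GSK343 too (-0.13), and a change in their own level could hide such an effect. MALAT1, which also lacks a tail, was at 0.35 to 0.91 by its 5 probes, and ND6 was higher too. Both go with this explanation but cannot decide it, since MALAT1 was chosen and ND6 known before the explanation was tested. Cultures and array positions cannot be told apart from the compound with 1 array per group, and the COX1 probe is placed by the files on chromosome 1.

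Many more genes were 2-fold lower than higher with UNC1999. A trend with signal was argued against as the whole cause, since cyclic loess left 4.4516 lower genes per higher gene. Nearness to the background stayed open: 93.4426% of the 244 lower genes lay under the median signal, but so did 18 of the 22 higher genes, and above it 4 were higher and 16 lower. With normexp background correction 3 genes were higher and 17 lower, so most of both counts depended on how the background was handled. No biological explanation was tested.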

How the results depend on the processing

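The sets of genes with a symbol, genes above the 75th percentile, the narrower pool and the further draws of random lists were chosen after seeing the data; other alternatives were planned. Of the medians of the 6 leading lists in 3 comparisons, 118 values under alternatives kept their sign and stayed near, 15 moved with their sign kept, 6 that lay inside their random range moved across 0 and 5 that lay outside it changed sign; of the values of named genes, 3647 stayed within their scanner error and 43 moved further. The cause was not tested for any value below, except that fewer genes are counted under a stricter filter and that a single factor per array moves all genes alike in the unscaled and median-scaled values. Counts are given as higher and lower.

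UNC1999 against control gave 22 and 244 genes, but 3 and 17 with normexp, 40 and 126 with quantile normalization, 138 lower with cyclic loess, 147 lower with median scaling, 12 and 503 unscaled, 57 and 504 without a filter, 4 and 16 above the median signal, 12 and 106 with a symbol and 277 and 1534 at 1.5-fold. GSK343 against control gave 30 and 119, but 2 and 25 with normexp, 50 higher with quantile normalization, 47 higher with cyclic loess, 18 and 214 unscaled, 80 and 369 without a filter, 0 and 20 above the median signal, 13 and 49 with a symbol and 236 and 858 at 1.5-fold. UNC1999 against GSK343 gave 44 and 66, but 7 and 3 with normexp, 172 and 216 without a filter, 5 and 1 above the median signal, 20 and 38 with a symbol and 386 and 701 at 1.5-fold. Shared by both compounds were 3 and 41, but 0 and 7 with normexp, 82 lower unscaled, 14 and 134 without a filter, 0 and 7 above the median signal, 16 lower with a symbol and 39 and 385 at 1.5-fold. The correlation of 0.52 was 0.46 above the median signal and 0.40 above the 75th percentile, where simulated arrays gave 0.50.

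Unscaled, the UNC1999 medians were -0.062 (autophagy), 0.14 (integrated stress response), -0.031 (amino acid), -0.049 (ER), 0.29 (cholesterol), -0.18 (PRC2 targets) and -0.0072 (PRC2 subunits). Those of GSK343 were -0.077, 0.11, -0.063, -0.031, 0.044 and -0.18 for the first 6 of these lists, -0.054 (ERK output) and -0.10 (reference genes). With median scaling, autophagy, amino acid, ER and cholesterol medians were 0.18, 0.21, 0.19 and 0.53 for UNC1999 and 0.12, 0.13, 0.16 and 0.24 for GSK343. GSK343 also had 0.31 (integrated stress response), 0.013 (PRC2 targets) and 0.0022 (ribosomal proteins), the last being 0.0069 after cyclic loess. PRC2 targets with UNC1999 had 0.0235 with normexp, 0.0561 with median scaling and 0.10 above the median signal, and autophagy genes had -0.0009 between the compounds with the mean of all probes.

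Cholesterol medians ranged from 0.29 to 0.53 for UNC1999, 0.044 to 0.24 for GSK343 and 0.26 to 0.31 between them, and those of the integrated stress response from 0.14 to 0.38 and 0.11 to 0.31 against control. Percentiles near the ends of the range varied with the draw: over 20 further draws with the first and the narrower pool, autophagy with UNC1999 was outside in 8 and 9, ER genes with UNC1999 in 18 and 16, p53 targets with GSK343 in 20 and 19 and BCL2 family genes with GSK343 in 15 and 4. No paired analysis was possible because each group holds 1 array, and leaving out a replicate was not possible for the same reason. Signal over background limits the dim genes: the SD of UNC1999 ratios was 0.36 over the 7174 dimmest genes and 0.20 over the 7173 brightest.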

Other observations

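The test of probe pairs and the choice of MALAT1, NEAT1 and the mitochondrial set came after their values were seen, while the histone set and the test on respiratory chain genes were set beforehand. Replication-dependent histone mRNAs were lower on both treated arrays, with a median of -0.28 and 39 of 43 below 0 with UNC1999 and of -0.13 and 41 of 43 below 0 with GSK343. These medians were -0.19 and -0.067 with median scaling and -0.43 and -0.26 without scaling. Both first medians lay below every matched random list, and histone probes can share sequence with related histone genes. The G1/S list had medians of 0.014 and -0.011. MALAT1, a nuclear-retained RNA, had a log2 ratio of 0.91 with UNC1999 and 0.17 with GSK343 at its brightest probe, its 5 probes lying between 0.35 and 0.91 with UNC1999, and NEAT1 was at 0.54 and 0.26, its 3 probes lying between 0.12 and 0.56 and between 0.020 and 0.26.

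The hypothesis that the lower mitochondrial mRNAs with UNC1999 reflect lower RNA of the respiratory chain as a whole, by as much in the nuclear subunits, was argued against. Nuclear-encoded subunits had a median of -0.030 over 75 genes, above the highest mitochondrial value of -0.19, though 47 were below 0 and the median lay at percentile 0.86 of its random lists. It was 0.058 with median scaling. With GSK343 the median was -0.057, at percentile 0.010, but -0.017 after cyclic loess, -0.011 after quantile normalization and 0.0064 with median scaling. ND1 was at -0.65 by both of its probes with UNC1999.

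Noise of single probes was argued against as the only source of the ratios with UNC1999. Across 1258 genes with both of their brightest probes above the 75th percentile, the ratios of these probes correlated with r = 0.4072. Over all 5810 genes with another measured probe, r was 0.19, and both values include the error that probes share on an array.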
